A study of Mus musculus with 8 samples.

How the data were processed

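Chromatin accessibility was profiled by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA, in 8 libraries of common myeloid progenitor subpopulations from the bone marrow of wild-type C57BL/6 mice. Per the labels' protocols, each preparation started from 40000 to 50000 primary cells, which were treated with the transposase TDE1 in a buffer with digitonin. Groups were taken from the sample titles and the sorted surface phenotype, which give 4 populations of 2 libraries each: C2 (KIT+ CD16/32- CD34bright CD41+ CD9+), C18 (KIT+ CD16/32- CD34dim CD41+ CD9+ CD48dim), C13 (KIT+ CD16/32- CD34dim CD41- CD9-) and C10 (KIT+ CD16/32- CD34dim CD41+ CD9+ CD48bright). The series text names partly different clusters from the sample titles, so the names used here are those of the titles and rest on the sorted phenotype. The labels do not say whether the libraries of a population came from separate animals. The p-values of loci and of exact tests thus measure only the spread between these libraries, which may be technical.

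The authors' processed data are 16 peak lists, called separately in each library, on the mouse genome build mm10 per the submitters' processing notes, which also name Bowtie 1.0.0 and HOMER 1.0. Each library has a list in the layout of the peak caller F-Seq, whose version is not given in the sources used here. The deposited F-Seq lists give the peak height as a signal that F-Seq estimates from the read density of that library, and each holds 100000 peaks in falling order of signal, so that it ends at that number and not at a level of signal. Each library also has a HOMER list of 150-base peaks with unlabelled score columns as the authors deposited them. The authors' signal and score values were used only to rank peaks within a list. The lists hold no read counts, so the depth of the libraries is unknown and no counting interval is given. A longer HOMER list or a wider F-Seq peak can come from depth as well as from biology.

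The F-Seq lists were used as the main lists because their number of peaks varied less between libraries. Similarity of a pair of libraries was the Jaccard index, the bases under peaks of both lists divided by the bases under peaks of either. The mean index within populations was compared with that of all 105 ways of pairing the 8 libraries (exact permutation test, one-sided, smallest possible p = 0.0095). Consensus regions were the merged union of the 8 lists, and a region was called in a library when at least 1 base overlapped a peak. Regions called in both libraries of a population and in none of the others were its population-specific regions, and their number was ranked among all 28 pairs of libraries (exact test, one-sided, smallest possible p = 0.0357). The other populations are among these pairs, so only the highest-ranked population can reach this p.

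A locus was a protein-coding gene body of the RefSeq table for GRCm38.p6, the assembly of mm10, extended 10 kb to each side (21887 loci). Of the consensus regions, 29.8% lay in no locus and 14.6% in several, so neighbouring genes can share peaks. Where no caller is named, covered bases and the absence of a peak refer to the F-Seq lists. The bases of a locus under peaks were scaled to the mean total covered length, with factors from 0.885 to 1.43, and are given in kb with the SD over 2 libraries. Differences are on the log2(bases + 200) scale, which understates the change of loci with few covered bases. The 18458 loci covered in at least 2 libraries were tested with limma 3.58.1 (R 4.3.3), in 1 fit with 4 group means and eBayes with trend, and Benjamini-Hochberg adjustment at 0.05. Adjusted p-values of loci below come from this fit, which assumes the same spread of a locus in all 4 groups. Where the spread of a population differs, they can be too small or too large. The 3 contrasts were C2 against the mean of C10 and C18 (CD34), C13 against the mean of C10 and C18 (CD41 and CD9), and C10 against C18 (CD48). With all 8 libraries the median log2 difference of all loci was 0.06, -0.06 and -0.15 in these contrasts, and without scaling 0.17, 0.19 and 0.27, so list values are read against these medians.

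Gene lists for 11 classes were tested with camera in limma at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 33 combinations of list and contrast. At a preset correlation camera compares the loci of a list with all other loci. Its p-value then measures the spread between loci, not that between libraries. With an estimated correlation camera also limits its degrees of freedom to those of the libraries. A larger p-value there thus need not come from a higher correlation. The classes were stem and multipotent cells, megakaryocytes, erythroid cells, granulocytes and monocytes, mast cells with basophils and eosinophils, lymphocytes, macrophages, stroma with endothelium, haematopoietic transcription factors, housekeeping genes and non-haematopoietic genes. The transcription factor list shares Klf1 with the erythroid list, Spi1, Cebpa and Gfi1 with the granulocyte-monocyte list, Gata2 with the mast cell list, Nfe2 and Fli1 with the megakaryocyte list, Erg and Meis1 with the stem list and Runx2 with the stroma list. Genes named in the text are the 7 genes of the sort markers, the 10 loci with the smallest p in each direction per contrast that passed the adjustment and had the same sign in the HOMER lists, the 3 members with the smallest p per list and contrast, and the 10 loci with the most population-specific regions per population. Some genes that meet this rule are not reported here. Clone names, predicted genes and olfactory or vomeronasal receptors were left out of the loci ranked over the genome. The groups, tests, gene lists, naming rule and the first set of varied settings were fixed before the data were examined.

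Settings varied were the HOMER lists, peaks found by both callers, the 50000 strongest peaks of each list, other pseudocounts (20 and 1000 bases), filters, scalings and locus widths (50 kb), the number of peaks in place of bases, the replicate number as a block, an estimated correlation for the lists, and leaving out each library. Fits without the C18 libraries, locus fits with peaks of both callers and with the 20000 strongest peaks, and the share of peaks within 1 kb of a gene end were added after the data had been seen. Motif shares, the share of peaks at transcription start sites and loci made of promoters alone were not analysed here, since they need the genome sequence or the strand of genes. The fit was tested on simulated data for the C13 contrast over 18458 loci with 200 changed. It recovered 37% of loci changed by 1 and 86% of those changed by 2 on the log2 scale, with 6 false loci among 129 calls. All simulated libraries had the same spread at a locus, so these rates do not cover populations of unequal spread. The changed loci were never among those with the lowest mean coverage, and no group was set to be without peaks. The rates therefore do not cover loci without a peak in a whole population, as at several leading loci below. As a check of coordinates, 63.1% of genes had a peak of C13 replicate 1 at a gene end, against 22.3% after a shift of 20000 bases. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.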

Results

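Open chromatin was compared between 4 populations of common myeloid progenitors, the marrow cells that give rise to megakaryocytes, erythroid cells, granulocytes and monocytes. Each population was sorted as KIT+ CD16/32- cells and profiled in 2 libraries. C2 cells were CD34bright and carried CD41, the integrin alpha IIb chain of the megakaryocyte lineage, and CD9, a tetraspanin. The remaining populations were CD34dim. Of these, C13 lacked CD41 and CD9, C18 was CD41+ CD9+ with dim CD48, and C10 was CD41+ CD9+ with bright CD48, a receptor of the SLAM family.

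The F-Seq lists held 100000 peaks in every library and covered 89.7 ± 1.26 Mb in C2, 70.7 ± 11.6 Mb in C18, 99.1 ± 2.14 Mb in C13 and 96.8 ± 3.62 Mb in C10 (mean ± SD, n = 2 each). The C18 lists had the narrowest peaks, with a median of 491 bases in replicate 1 and 618 in replicate 2, against 691 to 800 bases in the 6 libraries of C2, C13 and C10. HOMER listed 72379 and 83548 peaks in the C18 libraries, 171712 and 196264 in C2, 252844 and 249132 in C13, and 235812 and 260118 in C10. A HOMER peak of the same library overlapped 42.5% and 42.0% of the F-Seq peaks of C18, 71.1% and 80.8% of those of C2, and 90.0% to 94.4% of those of C13 and C10. The depth of the libraries is unknown.

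Whether the sorted populations have distinct accessible chromatin was asked first from the overlap of whole peak lists. The C13 libraries were the most alike, with a Jaccard index of 0.796, followed by C10 (0.695), C2 (0.561) and C18 (0.390). Between populations, C13 and C10 shared most (mean 0.590 over 4 pairs of libraries). C2 stood closer to C10 (0.569) than to C13 (0.509), and C18 had the lowest indices, from 0.406 with C2 and 0.400 with C10 to 0.353 with C13. The mean index was 0.610 within populations and 0.471 between them. No other pairing of the libraries reached 0.610, the next giving 0.582 (exact permutation test, p = 0.0095, the smallest possible). In the F-Seq lists this order did not hold for each population, since the C18 libraries shared less with each other than C2 did with C18, and the C2 libraries less than C2 did with C10. With HOMER peaks it held for each, with 0.379 for the C18 libraries against 0.261 with C2, and 0.393 for the C2 libraries against 0.367 with C10. Without the C18 libraries the within-minus-between difference was 0.13 in place of 0.14, and its exact p of 0.0667 was the smallest that 15 pairings allow.

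**Figure D1:**
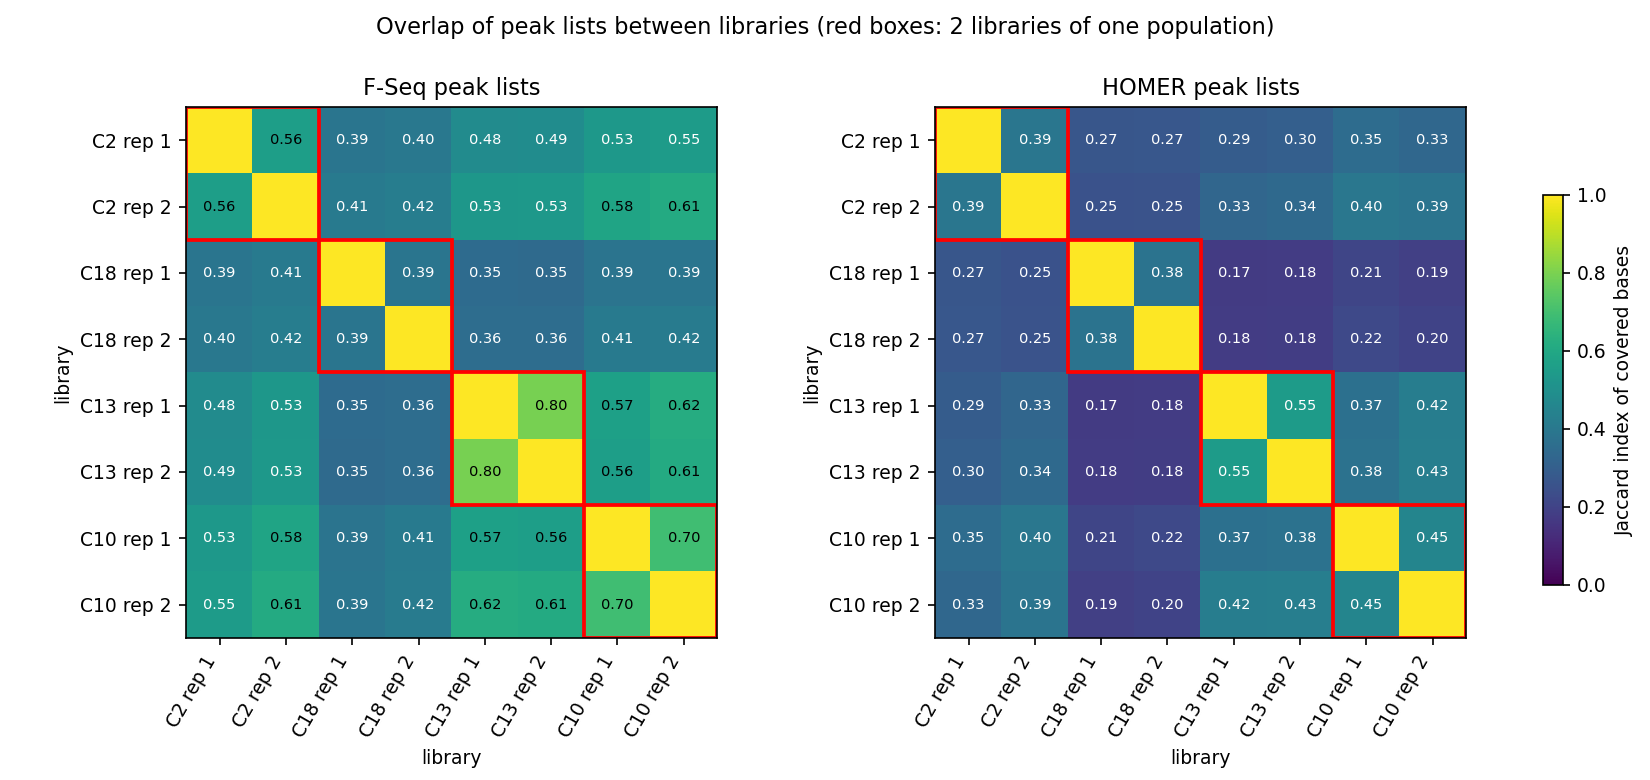
Heat maps of the Jaccard index of covered bases (colour scale, no unit) for each pair of the 8 libraries, for the F-Seq lists and for the HOMER lists, with red boxes around the 2 libraries of each population. In the F-Seq lists the C13 pair has the highest index (0.80) and the C18 pair the lowest of the boxed values (0.39).

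The CD41- CD9- population C13 had the largest set of regions of its own. Of 88234 regions called in both C13 libraries, 9774 (11.1%) had no F-Seq peak in any of the other 6 libraries. This was more than for any other of the 28 pairs of libraries (exact p = 0.0357, the smallest possible). At 40.8% of these C13-specific regions, however, HOMER listed a peak in another population. These regions were most numerous at Nav2, a neuron navigator gene (15 of 145 regions of the locus, chromosome 7, 48959063 to 49610090). They followed at Pakap and Hdac9, a class IIa histone deacetylase (11 each), and at Asic2, an acid-sensing ion channel, Lpp, a LIM domain protein, and the phosphodiesterase Pde4d (10 each). Ncald, Hivep3 and Foxp1, a transcription factor of B-cell development, held 9 each and Ctnnd2 8. All of these genes are long, and the number of regions grows with length. C18 had 2930 such regions (5.51% of 53171), led by the spindle checkpoint gene Mad1l1 (5 of 75) and by Fcnb, the myeloid lectin ficolin B, where 4 of the 10 regions were specific (chromosome 2, 28076479 to 28084910). Dnajc11, Eri3, Cyth3, Eif4g3, Clasp1, Aff3, Rabgap1l and Foxn3 also held 4 each.

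C10 had 2051 specific regions (2.51% of 81592). Of these, 5 lay at the RNA-binding protein gene Celf2, 4 each at Plxdc2, Nbea, Plcb1, Auts2 and the retinoic acid receptor gene Rarb, and 3 each at Nrg3, Chst9, P3h2 and Samd5. C2 had 1063 (1.57% of 67901). Runx1, the transcription factor required for the emergence of blood stem cells, held 5 of 78 (chromosome 16, 92601466 to 92826074). There were 5 at Gse1, 4 at Carmil1 and 3 each at Slc45a1, Nol4l, Celf2 and the ETS family gene Etv6. Actbl2 and the neighbouring genes Mmp19 and Tmem198b, which share peaks, held 2 each. The 4 populations led the 28 pairs in the order C13, C18, C10 and C2 (exact p = 0.0357, 0.0714, 0.107 and 0.143). The larger p-values reflect the other populations among the pairs, since each of the 4 lay above every pair of different populations. Pairs of libraries from different populations shared at most 833 private regions, with a median of 300. C13 and C10 together held 2761 regions found in no other library, C2 and C10 1044, C2 and C18 525, C18 and C10 480, C2 and C13 256, and C18 and C13 71. A HOMER peak lay in both libraries at 88.8% of the C13-specific and 82.1% of the C10-specific regions, but at 30.1% of those of C2 and 9.01% of those of C18. Over all regions of a population this share was 94.53% in C13, 93.16% in C10, 83.96% in C2 and 56.15% in C18. HOMER also listed a peak in another population at 43.44% of the C10-specific, 33.96% of the C2-specific and 18.84% of the C18-specific regions. With the HOMER lists C13 held 23373 specific regions, C10 6913, C2 1163 and C18 446, and pairs of different populations up to 3261. Without the C18 libraries the numbers were 10734 for C13, 3585 for C10 and 2315 for C2. Where 1 library of a population is left out, regions of the remaining library count as specific. This gave 9227 without C2 replicate 1 and 15509 without replicate 2, 27914 and 25691 for C18, and 4220 and 6967 for C10.

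**Figure D2:**
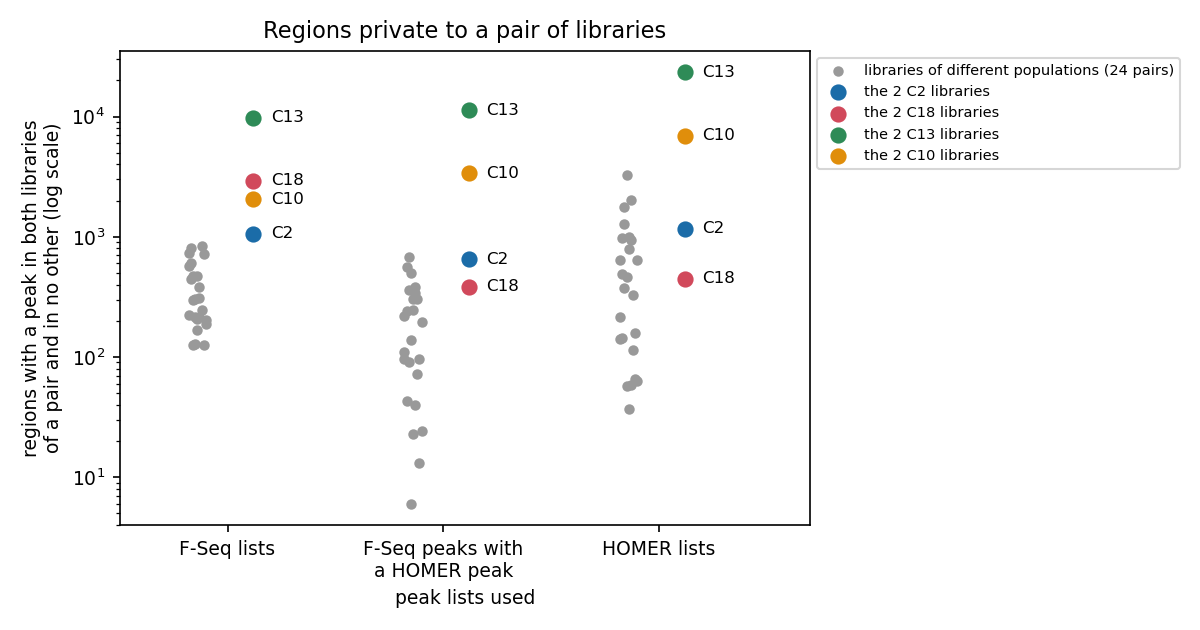
Number of regions with a peak in both libraries of a pair and in no other library (vertical axis, log scale), by the peak lists used (horizontal axis). Coloured points are the 2 libraries of 1 population and grey points the pairs of different populations, and in the F-Seq lists the C13 pair (9774) lies above all others while the highest grey point is 833.

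Of the loci of the 7 genes that encode the sort markers, none followed the sorted phenotype past the threshold in the F-Seq lists. In the HOMER lists Itga2b, Cd9 and Cd48 passed in the sorted direction. For Itga2b and Cd9, however, C10 lay nearer to C13 than to C18 there. Itga2b had 0.86 kb under HOMER peaks in C13, 1.06 kb in C10 and 2.62 kb in C18, and Cd9 1.31, 1.77 and 3.08 kb. Kit, the stem cell factor receptor, was covered over 7.46 ± 0.87 kb in C2, 9.23 ± 0.63 kb in C18, 9.03 ± 1.69 kb in C13 (SD, n = 2), and over 5.95 and 10.2 kb in the C10 libraries. Itga2b, which encodes CD41, had 2.77 ± 0.09 kb in C13, 2.92 ± 0.13 kb in C10, 4.73 ± 0.73 kb in C18 and 4.52 ± 1.45 kb in C2, and Cd9 8.59 ± 0.47, 9.23 ± 0.02, 10.3 ± 0.48 and 9.78 ± 2.04 kb in the same order. Neither passed the test of C13 against C10 and C18 (adjusted p = 0.265 for Itga2b and 0.433 for Cd9). In the HOMER lists both were lower in C13 (log2 -0.85, adjusted p = 0.0379, and -0.75, adjusted p = 0.0156), where the housekeeping loci had a median of -0.65. They were also lower there in C10 than in C18 (-1.16, adjusted p = 0.0108, and -0.73, adjusted p = 0.0124), although both populations are CD41+ CD9+. In that comparison the housekeeping loci had a HOMER median of -1.18, with 16 of 18 lower. Cd48 had 5.11 ± 0.12 kb in CD48bright C10 and 3.28 ± 0.82 kb in CD48dim C18 (log2 difference 0.63, SE 0.185, adjusted p = 0.0501), and was higher in C10 in the HOMER lists (0.71, adjusted p = 0.0365). Cd34 was covered over 13.2 and 10.8 kb in CD34bright C2, 13.6 ± 0.38 kb in C10 and 6.29 ± 0.92 kb in C18. It did not separate C2 from C10 and C18 (log2 0.37, adjusted p = 0.246) but was higher in C10 than in C18 (log2 1.09, SE 0.153, adjusted p = 0.00905). In the HOMER lists that last difference had the opposite sign (-1.09, adjusted p = 0.00387), with adjusted p from 0.00331 to 0.309 over 21 alternatives. The neighbouring receptor genes Fcgr3 and Fcgr2b, whose products are CD16 and CD32, passed in none of the 3 contrasts with the F-Seq lists, with log2 differences from -0.41 to 0.30 for Fcgr3 and from -0.09 to 0.39 for Fcgr2b. Fcgr3 was lower in C10 than in C18 in the HOMER lists (-1.26, adjusted p = 0.00811). The HOMER differences of Fcgr3 and Cd34 between C10 and C18 were near the housekeeping median of -1.18.

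The comparison of C13 with C10 and C18 asked which loci differ with CD41 and CD9 among CD34dim cells. Rab27b, a small GTPase of platelet dense granule secretion, was covered over 3.31 ± 0.49 kb in C13, 15.3 ± 2.00 kb in C10 and 10.9 ± 0.16 kb in C18 (SD, n = 2; log2 difference -1.91, SE 0.127, adjusted p = 0.00563; chromosome 18, 69979131 to 70141633). Among erythroid genes, Alas2, the first enzyme of haem synthesis in red cell precursors, had 0.41 ± 0.09 kb in C13 against 2.22 ± 0.08 kb in C10 and 1.88 ± 0.58 kb in C18 (log2 -1.88, SE 0.256, adjusted p = 0.0135). Irf8, a transcription factor of monocyte and dendritic cell development, went the other way, with 13.7 ± 2.20 kb in C13, 3.54 ± 1.58 kb in C10 and 3.67 ± 2.60 kb in C18 (log2 1.98, SE 0.445, adjusted p = 0.0446; chromosome 8, 120736358 to 120756694). So did Ebf1, which specifies the B-cell lineage, with 18.8 ± 1.31 kb against 12.2 ± 1.16 and 8.90 ± 1.75 kb (log2 0.85, SE 0.160, adjusted p = 0.0285). The adjusted p of Irf8 ranged from 0.00824 to 0.684 over 21 alternatives and missed 0.05 in 11 of them, and that of Rab27b reached 0.0648 in 1 of 22, without C13 replicate 2. Alas2 lost its call in 6 of 22 alternatives (adjusted p from 0.000457 to 0.189), and Ebf1 in 8 of 22 (0.00868 to 0.790), among them the fit without the C18 libraries. Of the 43 called genes that the naming rule gave in this contrast, 25 lost their call in the HOMER lists and 38 with a library left out. Those that lost it in no alternative were Klk1b9, Klk1b1, Duxbl2 and Duxbl3, of uncertain read placement, which were tested in 18 alternatives each and not with a C13 library left out. None had an F-Seq peak in C2, C10 or C18, so only the C13 libraries gave these loci a spread. Their small p-values in the F-Seq lists can rest on this.

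In all, 574 of 18458 loci were higher and 691 lower in C13 (limma, Benjamini-Hochberg adjusted p under 0.05). Counts of list members below are read against these numbers. The 10 lower loci with the smallest p were, besides Rab27b, Adamts5, Mlip, Epgn, Ankrd36, Agtr1a and Efhc2, each without an F-Seq peak in either C13 library, and Ndst3, Aldh1a1 and Colec11. HOMER listed peaks in C13 at each of these 6 loci, and there only Adamts5 passed (-1.41, adjusted p = 0.00796), while adjusted p was 0.125 to 0.732 for the others. Adamts5, an aggrecan-cleaving protease, was covered over 4.42 ± 0.30 kb in C10 and 3.46 ± 0.85 kb in C18 (adjusted p = 0.0023). Aldh1a1, a retinaldehyde dehydrogenase, had 0.52 ± 0.01 kb in C13 against 5.07 ± 0.71 and 4.47 ± 1.13 kb (log2 -2.77, SE 0.195). Ndst3, a heparan sulfate sulfotransferase, fell by 2.14 (SE 0.147) and the collectin gene Colec11 by 2.34 on the log2 scale (SE 0.193). The higher loci were led by Hpgd, the prostaglandin-degrading dehydrogenase (5.50 ± 0.40 kb in C13, 2.31 ± 0.04 kb in C10, no peak in C18), the histone variant gene Macroh2a1 (log2 2.28, SE 0.189), Ctnnd2 (1.21), Kank1 (1.04), Tox2 (1.07) and the neuronal factor gene Neurog1, which had F-Seq peaks in C13 and C2 but none in C10 or C18, while HOMER listed peaks in C10. Macroh2a1 had 22.6 ± 3.93 kb in C13 but also 18.2 ± 1.53 kb in CD41+ CD9+ C2, and did not pass in the HOMER lists (0.61, adjusted p = 0.235). Klk1b9 and Klk1b1 are paralogs with overlapping extended loci, and Duxbl2 and Duxbl3 are near-identical copies. In the F-Seq lists these 4 had peaks in C13 alone, while HOMER also listed peaks at each of them in C10. They are uncertain, since reads of one copy can be placed at another.

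Of 29 erythroid loci tested, 10 were lower and 0 higher in C13, and 17 were lower when adjusted over the list alone (camera adjusted p = 3.23e-08; adjusted p = 0.283 with an estimated correlation). Besides Alas2 they included Gypc, the membrane protein glycophorin C (log2 -0.85, SE 0.118), and Trim10, which had no peak in C13 and whose difference was 0.06 in the HOMER lists. Of 28 megakaryocyte loci, 7 were lower and 0 higher, 9 adjusted over the list alone (camera adjusted p = 0.00937; adjusted p = 0.233 with an estimated correlation). Among them were Rab27b, the platelet glycoprotein gene Gp9 (3.29 ± 0.03 kb against 5.07 ± 0.26 and 6.54 ± 0.12 kb, log2 -0.77, SE 0.113) and Treml1, a receptor of platelet granules with no peak in C13. The call of the megakaryocyte list ended in 2 of 22 alternatives, the number of peaks and the 20000 strongest peaks (camera adjusted p up to 0.347). The call of Gp9 ended in 11 of 22 alternatives, among them the HOMER lists (-0.19, adjusted p = 0.613), no scaling and peaks of both callers, with adjusted p from 0.00279 to 0.613. Haematopoietic transcription factor loci were lower at 4 of 24 genes, 5 adjusted over the list alone (camera adjusted p = 0.0225; adjusted p = 0.422 with an estimated correlation). They included the GATA1 partner Zfpm1 (log2 -1.21, SE 0.178), the erythro-megakaryocytic repressor Gfi1b (-1.17, SE 0.191) and Gata2 (-1.06, SE 0.167; 0.06 in the HOMER lists). The transcription factor list lost its call without scaling, where its median was 0.03 against 0.19 for all loci, and without the C18 libraries, among others, with adjusted p from 0.00141 to 0.743 over 22 alternatives. Housekeeping loci, which serve as a control, had a median of -0.24 with 1 of 18 lower, Eef2, and 0 of 18 adjusted over the list alone (camera adjusted p = 0.105). However, 9 of 18 were lower in the HOMER lists (median -0.65, camera adjusted p = 0.000385). The erythroid median was -0.64 there with 12 of 29 lower, and the megakaryocyte median -0.29 with 6 of 28 lower and 1 higher. Neither list thus lay below the control there. The HOMER level of the control relative to all loci was 0.98 in C18, -0.02 in C10 and -0.07 in C13, so this control median rests on C18. Without scaling the housekeeping median was 0.02, the erythroid -0.40 and the megakaryocyte -0.07.

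Lymphoid loci were higher in C13 at 5 of 23 genes and lower at 0, and at 11 when adjusted over the list alone (camera adjusted p = 1.36e-05; adjusted p = 0.205 with an estimated correlation). They included Ebf1 and the T-cell adhesion gene Cd2 (10.8 ± 0.06 kb against 6.49 ± 1.42 and 2.33 ± 0.17 kb, log2 1.43, SE 0.224). Stroma and endothelium loci were higher at 4 of 17 genes, 6 adjusted over the list alone (camera adjusted p = 0.000494; adjusted p = 0.205 with an estimated correlation), with the endothelial cadherin gene Cdh5 (log2 1.15, SE 0.165), the chemokine gene Cxcl12 (1.21, SE 0.212) and Kitl, the ligand of KIT (1.07, SE 0.193). Macrophage loci were higher at 2 of 15, 4 adjusted over the list alone (camera adjusted p = 0.00606; adjusted p = 0.233 with an estimated correlation), namely the scavenger receptor gene Marco (1.17, SE 0.212) and the complement gene C1qa (1.04, SE 0.224). The granulocyte-monocyte list did not move as a whole (camera adjusted p = 0.919, with a median of 0.05 and a mean of -0.11). Irf8 and the lactoferrin gene Ltf (1.06, SE 0.217) were higher and 2 members lower, among them Ms4a3 (-2.09, SE 0.203), a gene of granulocyte-monocyte progenitors. The list had 3 higher and 5 lower adjusted over the list alone. Nor did the stem and multipotent list pass (adjusted p = 0.350). Of its 24 genes 2 were lower, 2 adjusted over the list alone, among them the angiopoietin receptor gene Tek (-2.20, SE 0.220). In the mast cell, basophil and eosinophil list (adjusted p = 0.287) 3 of 18 were lower, 3 adjusted over the list alone. They were Gata2, the mast cell protease gene Cpa3 (-0.89, SE 0.155, but 0.60 in the HOMER lists) and Ms4a2, the beta chain of the IgE receptor (-1.38, SE 0.311). The call of Ms4a2 ended in 12 of 22 alternatives, among them the HOMER lists, no scaling and the replicate number as a block. Of 19 non-haematopoietic loci Neurog1 was higher and Gfap lower, also when adjusted over the list alone by number, 1 and 1 (camera adjusted p = 0.192). The call of Gfap ended in 14 of 22 alternatives, among them the HOMER lists (-0.18, adjusted p = 0.426) and the replicate number as a block. The median of the non-haematopoietic list, a control, was 0.41, near that of the stroma list (0.39). In the HOMER lists this control list was called, with 5 higher and 0 lower (camera adjusted p = 0.00141). The higher lymphoid, stroma and macrophage lists are therefore uncertain, although without the C18 libraries the control median was 0.01.

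Of the 1265 loci that differed in C13, 1106 (87.4%) had the same sign in the HOMER lists, where 4364 loci passed, and 92 had no peak in either C13 library. The number of calls fell to 14 without C13 replicate 1, 1 without C13 replicate 2, 177 without C10 replicate 1 and 227 without C10 replicate 2, and reached 3492 and 2560 without C18 replicates 1 and 2. Without scaling 83.7% of the calls were higher in C13, in place of 45.4%. Without the C18 libraries, C13 against C10 alone gave 387 higher and 490 lower loci. There the megakaryocyte list (6 lower, adjusted p = 1.44e-05), the erythroid list (6 lower, adjusted p = 1.48e-05) and the lymphoid list (3 higher, adjusted p = 0.00503) passed again, as did the stroma and endothelium list (1 higher, adjusted p = 0.0220). With an estimated correlation their adjusted p was 0.247, 0.247, 0.342 and 0.265. The erythroid median was -0.31 there, in place of -0.65, with 6 of 29 lower in place of 10, and 7 in place of 17 adjusted over the list alone. The mast cell list (4 lower, adjusted p = 0.0167) and the stem and multipotent list (2 lower, adjusted p = 0.0186) passed here and not with all 8 libraries (adjusted p = 0.265 for each with an estimated correlation). The macrophage list (adjusted p = 0.0552) and the transcription factor list (adjusted p = 0.110) did not pass.

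**Figure D3:**
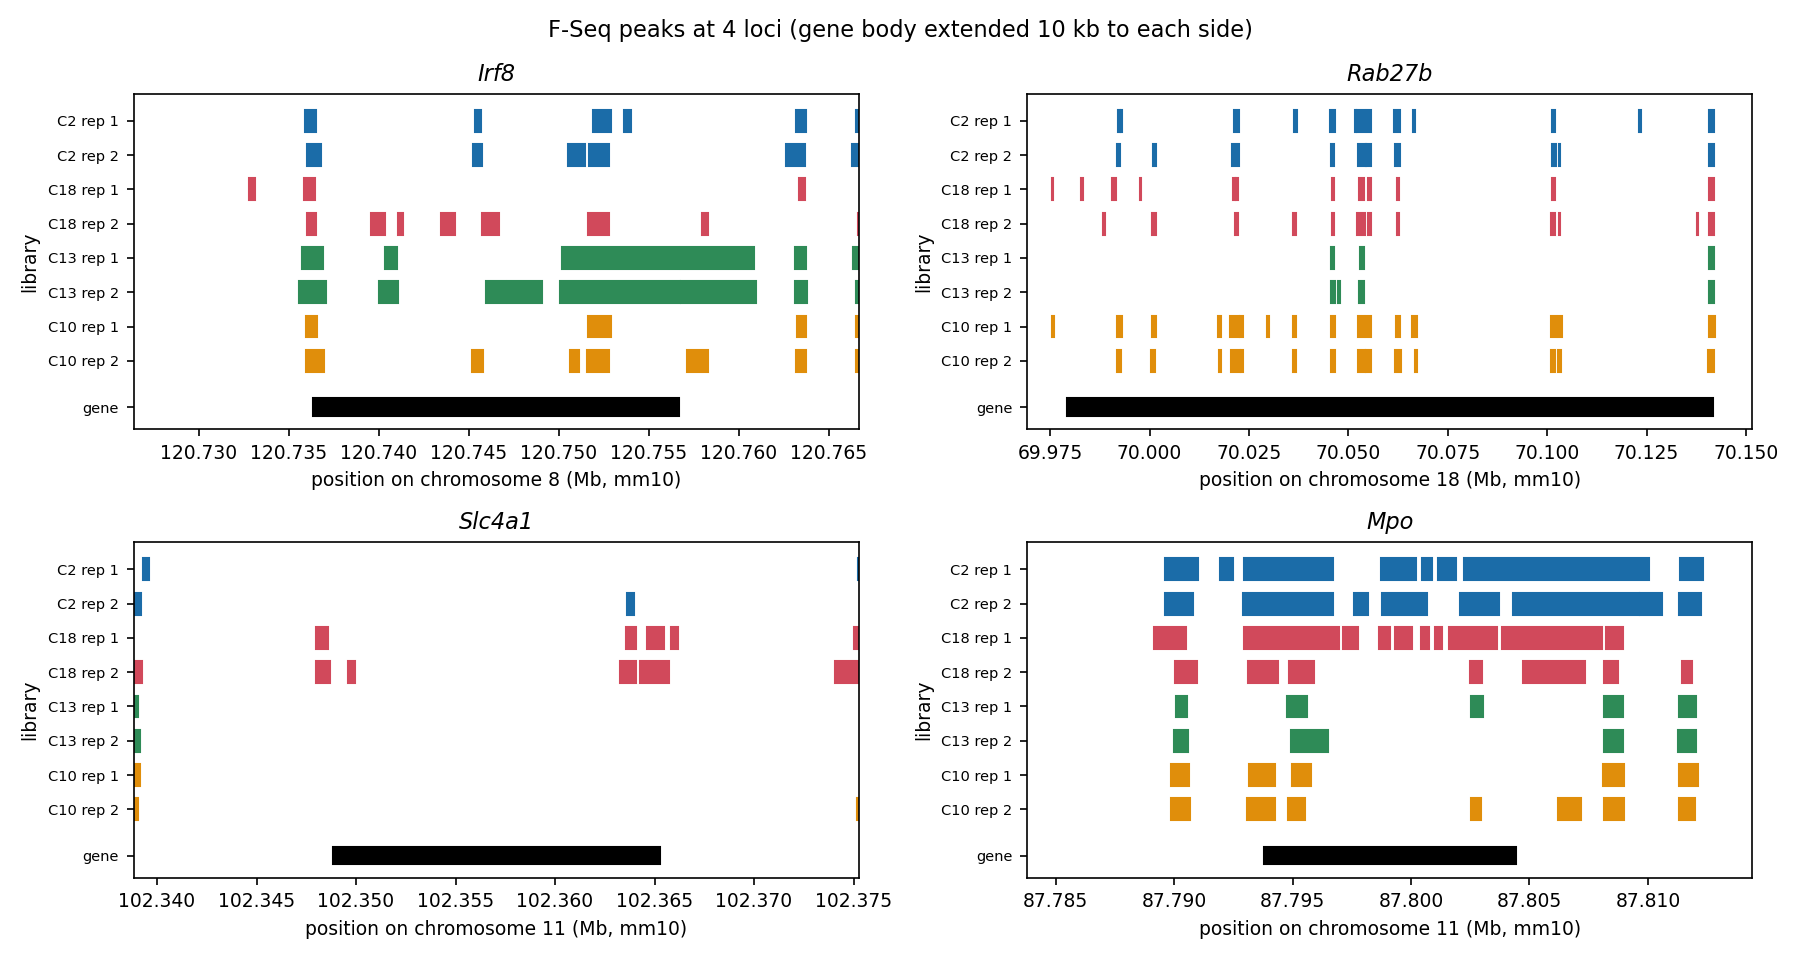
F-Seq peaks (coloured bars, 1 line per library) at Irf8, Rab27b, Slc4a1 and Mpo along the chromosome (Mb, mm10), over the gene body (black bar) and 10 kb to each side. Wide peaks at the Irf8 locus in both C13 libraries and few peaks at Rab27b in C13 are seen, with unscaled widths.

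C10 against C18 compared CD48bright with CD48dim cells among CD34dim CD41+ CD9+ progenitors. Slc4a1, the band 3 anion exchanger of red cells, was covered over 4.65 ± 1.46 kb in C18 and 0.33 ± 0.00 kb in C10 (SD, n = 2; log2 difference -3.17, SE 0.366, adjusted p = 0.00702; chromosome 11, 102348820 to 102365281). Fcnb was also lower in C10, with 1.60 ± 0.09 against 7.30 ± 0.06 kb (log2 -2.06, SE 0.185, adjusted p = 0.00615). Higher in C10 were the mast cell protease gene Cpa3, with 5.01 ± 0.05 against 1.44 ± 0.15 kb (log2 1.68, SE 0.179, adjusted p = 0.00673; chromosome 3, 20215616 to 20242209), and Il5ra, the interleukin 5 receptor chain of eosinophils and basophils (8.91 ± 1.30 against 1.89 ± 1.04 kb, log2 2.21, SE 0.318, adjusted p = 0.00938). Mecom, a regulator of blood stem cells, had 40.1 ± 2.14 against 20.4 ± 0.63 kb (log2 0.97, SE 0.145, adjusted p = 0.0103).

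In total 1462 of 18458 loci were higher and 2625 lower in C10 (limma, Benjamini-Hochberg adjusted p under 0.05). Together they were 22.1% of the tested loci, and 47.8% passed in the HOMER lists. Counts of list members below are read against these shares. Higher loci were led by Evx2, a homeobox gene beside the Hoxd cluster (6.26 ± 1.22 against 0.63 ± 0.05 kb, log2 2.95, SE 0.205), Lrrc4, the coagulation factor gene F9 (2.72, SE 0.208), Begain and Zic5. They also included Mep1a, Coch, Hpgd, Prdm6 and Lysmd2, none of which had a peak in C18. The lower loci with the smallest p were Slc25a42, a mitochondrial coenzyme A carrier (2.30 ± 0.32 against 11.3 ± 0.36 kb, log2 -2.20, SE 0.174), the phosphatase gene Ptpn11 (-1.91, SE 0.152), the adjacent genes Nme3 and Mrps34, which share peaks, Fcnb, Tmc6 and Ifi30, a lysosomal thiol reductase (-1.13, SE 0.108). Slc5a2, Inf2 and Smok2a, also among them, had no F-Seq peak in C10. HOMER listed C10 peaks at Inf2 and Smok2a, and Smok2a did not pass there (adjusted p = 0.0768).

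Of 29 erythroid loci 7 were lower and 0 higher in C10, 8 lower adjusted over the list alone (camera adjusted p = 0.0144; adjusted p = 0.484 with an estimated correlation). Among them were Slc4a1, the Rhesus antigen gene Rhd (1.73 ± 0.33 against 7.21 ± 1.73 kb, log2 -1.93, SE 0.306) and the spectrin gene Sptb (-0.87, SE 0.207). This call ended in 4 of 21 alternatives, namely 50 kb on each side, the number of peaks, the 20000 strongest peaks and without C18 replicate 2, with adjusted p from 0.0016 to 0.376. The erythroid list had the highest level in the C18 libraries, above all 6 others in the F-Seq and the HOMER lists (exact p = 0.0357 over 28 pairs, the smallest possible). In the HOMER lists the housekeeping and transcription factor lists did so too (exact p = 0.0357 each). The C18 level there exceeded the other libraries by 0.820 for erythroid, 0.928 for housekeeping and 0.705 for transcription factor loci. The HOMER result is therefore not particular to erythroid loci. Transcription factor loci were lower at 7 of 24, 9 adjusted over the list alone, with 1 higher (camera adjusted p = 0.0790). They included Nfe2, a subunit of the NF-E2 factor of megakaryocytes and red cells (-0.84, SE 0.125), Cbfa2t3 (-1.01, SE 0.179) and Runx1 (-0.87, SE 0.157). Housekeeping loci moved the same way, with 3 of 18 lower, Tubb5 and Actb among them, also 3 adjusted over the list alone, and a median of -0.44 (camera adjusted p = 0.0790). In the HOMER lists 16 of 18 housekeeping loci and 15 of 29 erythroid loci were lower. Without scaling the transcription factor list turned to a median of 0.14 with 3 higher and 0 lower and the housekeeping list to 0.00, against 0.27 for all loci. Of 26 granulocyte-monocyte loci 5 were lower and 1 higher, equally many adjusted over the list alone. Among them were the antimicrobial peptide gene Camp, without a peak in C10, and S100a8 (-2.88, SE 0.458). That list was not called (adjusted p = 0.350), and its median was -0.21, but 0.21 without scaling. Its levels ranged from 0.05 to 0.69 in C18, with 21.2 kb covered at Mpo, the myeloperoxidase gene, in replicate 1 and 8.37 kb in replicate 2.

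Lymphoid loci were higher in C10 at 6 of 23 genes and lower at 1, with 6 and 3 adjusted over the list alone (camera adjusted p = 0.0206; adjusted p = 0.239 with an estimated correlation). Examples are the recombinase gene Rag2 (9.06 ± 0.29 against 3.16 ± 1.45 kb, log2 1.53, SE 0.275), Cd2 (1.39, SE 0.258) and Dntt, the terminal transferase gene (1.00, SE 0.204). Stroma and endothelium loci were higher at 4 of 17, 4 adjusted over the list alone (camera adjusted p = 0.0206; adjusted p = 0.239 with an estimated correlation), with Kitl (1.31, SE 0.223), Cxcl12 (1.19, SE 0.244) and the growth factor receptor gene Pdgfra (0.94, SE 0.202). The macrophage list passed with 1 of 15 higher, 1 adjusted over the list alone, Marco (1.28, SE 0.245; camera adjusted p = 0.0206; adjusted p = 0.239 with an estimated correlation). That count is not above the share of all tested loci called higher in C10. The macrophage list had a median of 0.62, against -0.15 for all loci. These calls of the lymphoid, stroma and macrophage lists ended without scaling, with adjusted p of 0.0721, 0.0798 and 0.0956, and ranged up to 0.183, 0.376 and 0.249 over 21 alternatives from 0.000516, 0.00282 and 0.00114. The stem and multipotent list was not called (4 of 24 higher, 4 adjusted over the list alone, adjusted p = 0.0968), with Mecom and Mllt3 (0.83, SE 0.196) among the higher ones. Nor was the megakaryocyte list (3 higher and 2 lower of 28, the same adjusted over the list alone, adjusted p = 0.0872), with Cd226 higher (1.13, SE 0.165) and the platelet glycoprotein gene Gp1ba and Nfe2 lower (-1.20, SE 0.155, for Gp1ba). The mast cell list had Cpa3 and Il5ra higher of 18, 2 adjusted over the list alone (adjusted p = 0.222, with a median of -0.11, or 0.34 without scaling, and a mean of 0.03). It was called in the HOMER lists, with 11 higher, 0 lower and a median of 0.72 (adjusted p = 0.000385). Of 19 non-haematopoietic loci 4 were higher, with Sox2 among them (1.74, SE 0.373). Lower were 2, Gfap (-1.27, SE 0.187) and Krt5 (no peak in C10; 0.66 in the HOMER lists), with 5 and 2 adjusted over the list alone and a median of 0.76 (adjusted p = 0.0790). HOMER peaks gave a call of the non-haematopoietic list as higher (adjusted p = 0.0019), and of the transcription factor and housekeeping lists as lower (adjusted p = 0.000704 and 0.000384).

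Of the 4087 loci called between C10 and C18, 3392 (83.0%) had the same sign in the HOMER lists, where 8930 passed, and 160 had no peak in C18 and 179 none in C10. The number of calls was 0 without C10 replicate 1 (limma; 4534 loci at an unadjusted p under 0.05), 373 without C10 replicate 2, 1950 without C13 replicate 1 and 1955 without C13 replicate 2, whose spread enters the shared fit. Each of the 47 called genes that the naming rule gave in this contrast lost its call with some library left out, and 14 in the HOMER lists. Higher in C10 were 35.8% of the calls with the covered length scaled to its mean, 53.6% with quantile normalization and 87.4% without scaling.

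**Figure D4:**
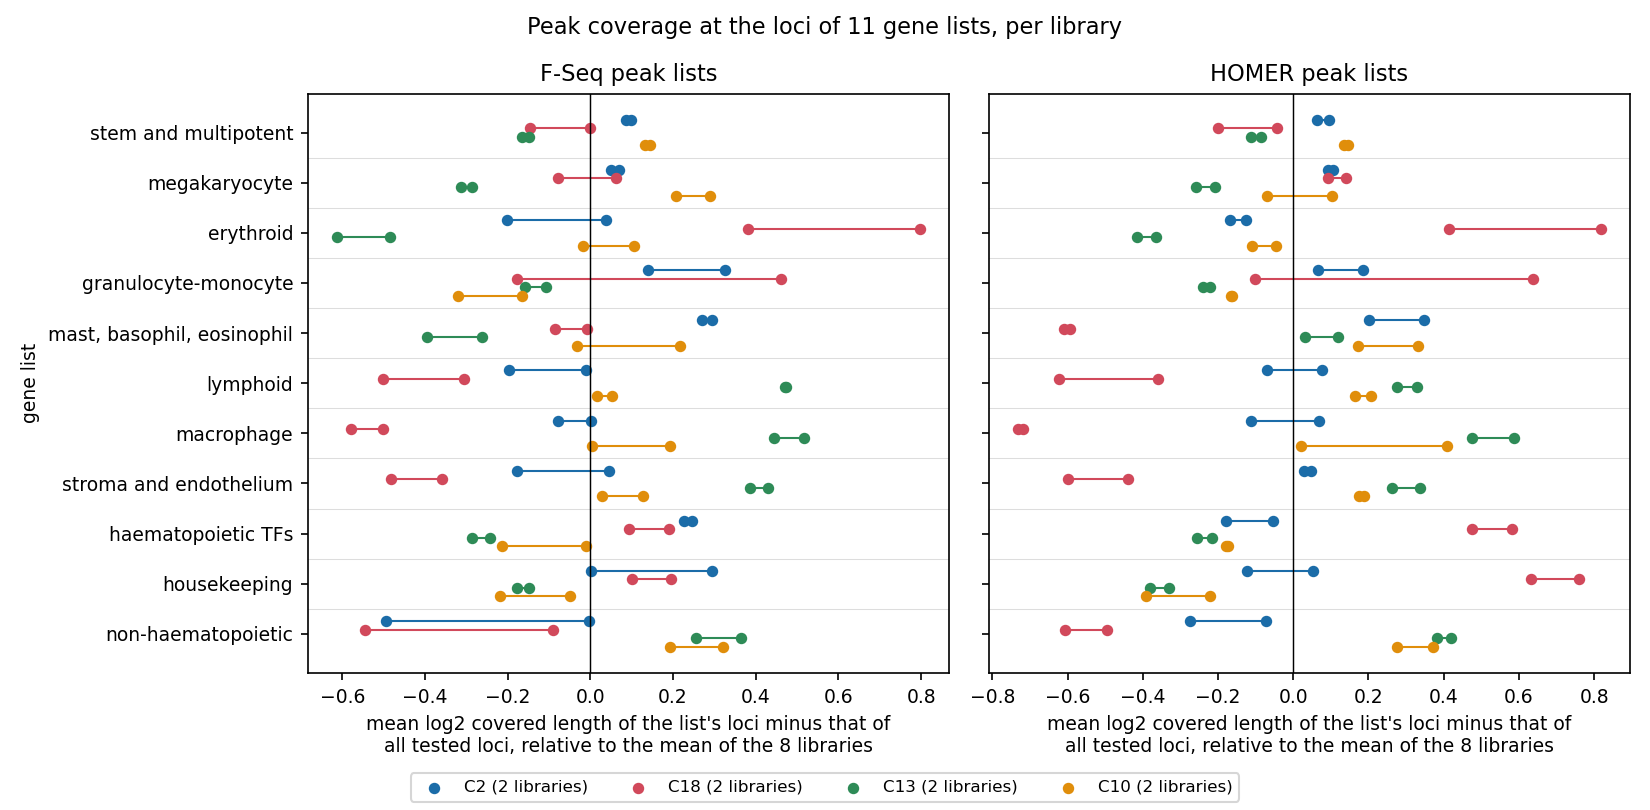
Mean log2 covered length over the loci of each of the 11 gene lists minus that over all tested loci (horizontal axis, relative to the mean of the 8 libraries), for the F-Seq lists (left) and the HOMER lists (right). Each point is a library and each line joins the 2 libraries of a population, with C13 lowest for the megakaryocyte and erythroid lists and C18 highest for the erythroid list in both panels. In the right panel C18 is also highest for the housekeeping and transcription factor lists.

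C2 against C10 and C18 compared CD34bright with CD34dim cells among CD41+ CD9+ progenitors, and no locus passed. Mpo had 16.6 ± 0.85 kb in C2, 4.58 ± 0.69 kb in C10 and 14.8 ± 9.04 kb in C18 (SD, n = 2; log2 difference 1.07, SE 0.325, adjusted p = 0.192; chromosome 11, 87793784 to 87804412). At Runx1 47.5 ± 1.69 kb were covered in C2, 22.0 ± 4.31 kb in C10 and 39.8 ± 0.96 kb in C18 (log2 0.69, SE 0.136, adjusted p = 0.121), and at Myb, a transcription factor of progenitor proliferation, 17.9 ± 5.67, 5.93 ± 1.09 and 8.90 ± 3.31 kb (log2 1.27, SE 0.260, adjusted p = 0.132). The erythroid gene Ank1, which encodes ankyrin 1 of the red cell membrane, had an adjusted p of 0.146 (log2 -0.55, SE 0.134). With limma 0 loci passed in the F-Seq and in the HOMER lists, while 3068 and 3048 had an unadjusted p under 0.05, and 595 passed without C18 replicate 1 and 321 without C18 replicate 2.

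As a set, the erythroid loci lay lower in C2, with 0 of 29 called, also adjusted over the list alone. Their median log2 difference was -0.22 (camera adjusted p = 2.15e-05, and 0.321 with an estimated correlation). This call ended in 2 of 22 alternatives, with 50 kb on each side and without the C18 libraries. The level of the list relative to all loci was 0.09 ± 0.17 in C2, 0.21 ± 0.09 in C10 and 0.76 ± 0.29 in C18 (SD, n = 2). The haematopoietic transcription factor list was higher, with a median of 0.22, 0 of 24 called and 2 adjusted over the list alone (camera adjusted p = 0.001; adjusted p = 0.302 with an estimated correlation). In the HOMER lists it was lower (median -0.23, adjusted p = 0.000704, with a range from 7e-05 to 0.368 over 22 alternatives). The granulocyte-monocyte list was higher with a median of 0.29 and 0 of 26 called, although Fcnb was lower when adjusted over the list alone (camera adjusted p = 0.0144; adjusted p = 0.508 with an estimated correlation). This call ended with the HOMER lists, without C2 replicate 2 and without C18 replicate 2, among others, with adjusted p from 1.19e-05 to 0.345 over 22 alternatives. The other 8 lists did not pass: adjusted p was 0.425 for the stem, 0.873 for the megakaryocyte (median 0.08, mean -0.03), 0.212 for the mast cell, 0.425 for the lymphoid, 0.726 for the macrophage, 0.733 for the stroma, 0.146 for the housekeeping and 0.192 for the non-haematopoietic list. With HOMER peaks the mast cell list (median 0.54, adjusted p = 0.000384) and the macrophage list (adjusted p = 0.0460) were called higher and the housekeeping list lower (median -0.24, adjusted p = 0.0052). Adjusted over the list alone, 2 mast cell genes were higher, and of the non-haematopoietic genes 1 was higher and 1 lower.

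Without the C18 libraries, C2 against C10 alone gave 1015 higher and 431 lower loci. Mpo was higher in C2 (log2 1.83, SE 0.138, adjusted p = 0.0288), as were its neighbour Lpo, the lactoperoxidase gene, which shares peaks with it (2.22, SE 0.185), Runx1 (1.12, SE 0.155, adjusted p = 0.0307), Myb (1.54, SE 0.235, adjusted p = 0.0310) and Runx3 (1.14, SE 0.223). Of 26 granulocyte-monocyte loci 8 were higher and 0 lower, 9 adjusted over the list alone (camera adjusted p = 0.00039; adjusted p = 0.346 with an estimated correlation). Of 24 transcription factor loci 5 were higher, 13 adjusted over the list alone (camera adjusted p = 0.000371; adjusted p = 0.346 with an estimated correlation). The granulocyte-monocyte members were Mpo, Camp, the transcription factor genes Cebpe and Spi1, the adjacent protease genes Elane and Prtn3, and the adjacent calprotectin genes S100a8 and S100a9, of which the adjacent ones share peaks. Housekeeping loci were higher as well, at 2 of 18, 4 adjusted over the list alone (camera adjusted p = 0.0220; adjusted p = 0.538 with an estimated correlation). Non-haematopoietic loci were lower, with a median of -0.43 and 1 of 18 higher and 1 lower, or 1 and 2 adjusted over the list alone (camera adjusted p = 0.0122; adjusted p = 0.265 with an estimated correlation). A difference in library quality can move these 2 control lists apart, so the other calls of this fit are uncertain. The erythroid list was not called (adjusted p = 0.158). These genes and lists were taken from this fit after its values had been seen.

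Peaks near gene ends were compared last. Within 1 kb of either end of a protein-coding gene lay 14.7 ± 0.14% of the F-Seq peaks of C2, 14.6 ± 0.15% of C18, 13.8 ± 0.04% of C13 and 13.9 ± 0.27% of C10 (SD, n = 2; exact permutation test over all pairings, p = 0.0667). In the HOMER lists, whose lengths differ, the shares were 26.1%, 36.3%, 20.6% and 21.1% in the same order (SD 0.946 to 2.18, n = 2; exact p = 0.0190). Within 5 kb the shares of the F-Seq peaks were 33.1%, 32.1%, 29.6% and 29.8% (exact p = 0.0476).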

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

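The groups hold 2 libraries each, so leaving out 1 leaves a population with a single library, and the cause of the changes below was not tested. Motif shares, the share of peaks at transcription start sites and loci of promoters alone were planned and not analysed here, since they need a genome sequence or strand. The replicate numbers did not pair libraries, as their correlations across populations ran from -0.013 to 0.121. With the replicate number as a block, 0 loci passed for C2, 1018 for C13 and 3705 for C10 against C18, and 13 gene lists. The within-minus-between similarity of 0.140 was 0.128 without the C18 libraries.

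Population-specific regions of C2 numbered 2315 without the C18 libraries, 648 with peaks of both callers and 608 with the 50000 strongest peaks, and 9227 to 15509 with 1 library left out. Those of C18 numbered 446 in the HOMER lists and 383 with peaks of both callers, and 25691 to 27914 with 1 left out. C13 had 23373 in the HOMER lists and 6384 with the 50000 strongest peaks. C10 had 3585 without the C18 libraries, 6913 in the HOMER lists, 3368 with peaks of both callers, 798 with the 50000 strongest peaks, and 4220 to 6967 with 1 left out.

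Loci called for C2 against C10 and C18 were 49 with a pseudocount of 20 bases, 167 with no filter, 3 if covered in at least 4 libraries, 15 with 50 kb on each side, and 438 by number of peaks. They were 145 with the 50000 and 1386 with the 20000 strongest peaks, 373 with peaks of both callers, 1446 without the C18 libraries, and 0 to 595 with 1 library left out. For C13 they were 4364 in the HOMER lists, 1904 with 50 kb, 2029 with the 50000 and 3022 with the 20000 strongest peaks, 3631 with peaks of both callers, and 1 to 3492 with 1 left out. For C10 against C18 they were 8930 in the HOMER lists, 7027 with 50 kb, 1212 by number of peaks, 8072 with peaks of both callers, and 0 to 5752 with 1 left out. Of the gene lists 13 were called, 0 with an estimated correlation, 21 in the HOMER lists and 4 with 50 kb. The share of peaks at gene ends in C2 minus that in C13 was 5.495 points in the HOMER lists and 3.519 within 5 kb, against 0.887, and in the HOMER lists C18 lay above C2.

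Some results took the opposite sign (log2). For C10 against C18 in the HOMER lists these were Fcgr3 (-1.255), Cd34 (-1.088) and Krt5 (0.660). Fcgr3 was also at -0.573 with 50 kb and -1.185 with peaks of both callers. Fcgr2b reached 3.439 and Mllt3 -0.334 with the 20000 strongest peaks, and Lrrc4 -1.105 with the 50000 strongest. For C13 in the HOMER lists these were Cd34 (-0.538), Trim10 (0.059), Gata2 (0.061) and Cpa3 (0.600), and C1qa was at -0.576 with the 50000 strongest peaks. For C2 in the HOMER lists the median of the transcription factor list was -0.228 and that of the housekeeping list -0.242.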

Other observations

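Peaks on the sex chromosomes were examined as a check of the animals used. Ddx3y, Uty and Eif2s3y, genes of the Y chromosome, had a peak in 8 of 8 libraries with both callers, and the neighbouring Kdm5d in 4 with F-Seq and 6 with HOMER. The X chromosome held 1.90 ± 0.10% of the F-Seq peaks of C2, 1.72 ± 0.07% of C18, 2.49 ± 0.03% of C13 and 2.56 ± 0.04% of C10 (SD, n = 2; exact permutation test, p = 0.0095). All 8 libraries thus have peaks at Y chromosome genes, and the cause of the different X shares was not tested.

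Of the tests of the C18-specific regions, that of their rank was chosen after the result was seen. The median rank of these regions was 54691 of 100000, so they do not lie mainly at the end of the lists. This rank cannot decide whether they are weak peaks, since HOMER support in C18 was already low there. For this, each list was cut into 10 equal parts by rank. In part 6, which holds this rank, a HOMER peak overlapped 14.3% and 15.4% of the C18 peaks. In the libraries of C2, C13 and C10 it overlapped 76.5% to 98.1% of the peaks in part 6. Calls of high rank that HOMER does not accept cannot be told apart from regions of the population. Of the 10000 strongest F-Seq peaks, 2.53% lacked a HOMER peak in the lower C18 library, against 0.03% to 0.36% in C2, C13 and C10. The support by HOMER relative to peaks of equal rank was 0.475 in C18 replicate 1 and 0.686 in replicate 2, on either side of the limit set before, so a biological origin cannot be told apart either.

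All tests of the many loci called between C10 and C18 were chosen after the result was seen. With the 20000 strongest peaks, 34.1% of the called loci that could be tested were called again with the same sign, so loss of weak peaks in C18 cannot be told apart from other causes. The share of peaks within 1 kb of a gene end was higher in C18 than in C10 by 0.636 points in the F-Seq lists, where C2 lay as high as C18, and by 15.2 points in the HOMER lists, so a shift of C18 peaks to gene ends by library quality cannot be told apart either. The erythroid median lay above the housekeeping median by 0.328 in the HOMER lists and below it by 0.048 in the F-Seq lists, so a difference between the CD48bright and CD48dim populations cannot be told apart from library quality.

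All tests of the lower coverage at erythroid and megakaryocyte loci in C13 were chosen after the result was seen, since the comparison planned before, of list medians relative to all loci, can hardly move with scaling and decides nothing. The C18 libraries are not its whole cause, since without them at least 6 members of each list were lower in C13 than in C10, but they carry part of the erythroid difference, whose median went from -0.65 to -0.31. Without scaling, the mean log2 level of the higher C13 library minus that of the lowest C10 or C18 library was -0.301 for the erythroid list, which scaling alone does not account for, but 0.341 for the megakaryocyte list, where scaling cannot be told apart from other causes. The C13 median lay below that of the housekeeping list in 2 of 4 combinations of list and caller, both with F-Seq. The HOMER medians were -0.64 (erythroid) and -0.29 (megakaryocyte) against -0.65. That comparison cannot tell a difference between the sorted populations from a change shared with housekeeping loci, since C18 lies in its reference. The HOMER housekeeping level relative to all loci was 0.98 in C18, but -0.07 ± 0.04 in C13 and -0.02 ± 0.12 in C10 (SD, n = 2). The erythroid level was -0.22 ± 0.03 in C13 and 0.09 ± 0.045 in C10, the megakaryocyte level 0.08 ± 0.04 and 0.33 ± 0.12. With F-Seq and without C18, their medians were -0.31 and -0.30. For C13 against C10 these values argue against a change shared with housekeeping loci. Housekeeping loci had a median of -0.24 with F-Seq but of -0.06 without the C18 libraries, with 0 of 18 lower, and a difference in depth was not tested.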
